A study of Homo sapiens with 6 samples.

How the data were processed

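Total RNA of human primary CD34+ haematopoietic stem and progenitor cells was measured on 6 Affymetrix arrays, 3 of cells with an empty vector (EV) and 3 of cells with a short hairpin RNA against DROSHA (shDrosha). Per the labels' protocols, 100 ng of RNA was labelled with a whole-transcript assay. The deposited table held 33297 rows of log2 values, 1 column per array, between 1.64 and 14.55. RMA and Partek made these values, per the submitters' processing notes, which state no version. No further normalization or centring was applied in the main comparison. Array medians ran from 6.80 to 6.84. Arrays correlated at 0.982 to 0.990 over the genes compared below, without those of the Y chromosome and the X-inactivation transcript. Over these genes 0 pairs of arrays held identical values. The files give no background level per probe set, and the number of arrays limits the precision.

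Rows were named by the annotation supplied with the array, in which 19460 rows had 1 gene symbol, 1754 several and 12083 no listed gene. Current symbols, gene types and neighbours came from a RefSeq table of assembly GRCh38.p14, in which 19429 of the 19460 rows matched by gene identifier. A gene with several probe sets (769 genes) kept the one with the highest mean over all 6 arrays, which gave 18417 genes. Genes on the Y chromosome and the X-inactivation transcript were not reported singly. Multi-copy genes share probes, and their values are uncertain.

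Groups were taken from the sample titles. Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 18417 genes and a threshold of 0.05. Confidence intervals are those of limma's moderated fit. DROSHA was also compared by a two-sided exact permutation test, whose smallest possible p is 0.1. Gene sets were compared with camera at a preset inter-gene correlation of 0.01, over the 25 lists fixed beforehand and, separately, over 173 microRNA genes. Camera was repeated with an estimated correlation, and fry was run for a rotation test of each set. Fisher's exact test was two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

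The titles number the replicates 1 to 3 in both groups. Deviations from the group means correlated at 0.289 to 0.381 between same-numbered arrays and at -0.252 to -0.114 between others, so the numbers were taken to pair the arrays. This pairing comes from the data, since the labels do not state one. The main fit had no block, as set beforehand, and a fit with the replicate number as a block stands beside it where it changes a call.

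The groups, the tests, the lists and the rule for named genes were set before the data were examined. The rule takes up to 12 genes per direction with the largest change among those past the threshold whose groups do not overlap. It fills up with the smallest unadjusted p among genes with an absolute log2 change of at least 0.58 and no overlap, and adds DROSHA, DGCR8 and up to 4 members of each list with the smallest p. Symbols of unnamed loci, pseudogenes and small RNA genes were counted and not named. MicroRNA genes were kept in the rule because they form a comparison of their own. A microRNA gene within 10 kb of another was counted to the same locus. A host is a protein-coding or, where stated, a noncoding gene whose span in the RefSeq table contains the microRNA gene. Strand was not considered, so a host may lie on the strand opposite the microRNA gene.

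The alternatives tried were centring each array on its median, repeated quantile normalization, leaving out the dimmest 30% of genes, an intensity trend or a robust prior in eBayes, array weights, the replicate block, the mean of a gene's probe sets, every row of the table, other thresholds, and leaving out each array in turn. The procedure was tested on simulated data with 200 changed genes among 18417. The fit recovered 29.9% of log2 changes of 0.5, 97.0% of 1 and 100% of 2, with 3 unchanged genes called, and with the block 26.9%, 97.0% and 100% with 7 unchanged genes called. The real fit called only 10 genes, so its adjustment was stricter and these shares may overstate its recovery. In it, MIR142 (log2 change 1.11) and LIPN (1.23) did not pass without the block. Of 25 simulated unshifted sets camera called 0, and a set shifted by 0.3 was found. Genes were simulated to vary independently, so this does not test calls on lists whose genes vary together. The G2/M list is such a list (estimated correlation 0.185), and its mean log2 change of 0.10 is smaller than the simulated shift. Sets of genes with seed sites for 26 microRNA families were planned and not run, because no transcript sequence was available.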

Results

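Gene expression was measured on 6 Affymetrix whole-transcript arrays from human primary CD34+ haematopoietic stem and progenitor cells, the blood-forming cells that can be grown for a time with haematopoietic cytokines. In 3 samples the cells carried an empty vector (EV), and in the other 3 a short hairpin RNA against DROSHA (shDrosha), the nuclear enzyme that cuts primary microRNA transcripts at their hairpins. Values were log2 expression values, with a median per array between 6.80 and 6.84, and the number of arrays limits the precision of every comparison. The labels do not say whether the replicates are separate donors or separate cultures, so the p-values measure only the spread between these samples.

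The first comparison asked whether the targeted transcript was lower in the shDrosha samples. DROSHA was lower on every shDrosha array than on any EV array. Its level was 7.74, 7.92 and 7.88 on EV arrays 1, 2 and 3, and 6.83, 6.97 and 7.01 on shDrosha arrays 1, 2 and 3. The mean fell from 7.85 ± 0.09 (SD, n = 3) to 6.94 ± 0.10 (SD, n = 3), a log2 change of -0.91 (SE 0.08). This left 53.3% of the EV level, with a 95% confidence interval of 46.6 to 60.9%. The limma adjusted p over all genes was 0.00856, and DROSHA was lower in 3 of 3 same-numbered pairs. The two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The adjusted p rose to 0.0574 without EV replicate 2, to 0.0571 without EV replicate 3 and to 0.0636 without shDrosha replicate 2, with log2 changes of -0.87, -0.89 and -0.93. It was 0.0956 when every row of the table was fitted, at the same log2 change.

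Around DROSHA, the list of microRNA processing and effector machinery held 18 genes, all of them measured. DROSHA was the only member past the threshold over all genes (1 lower), and 1 fell and 1 rose when adjusted over the list alone. The member that rose was DGCR8, the RNA-binding partner of DROSHA, whose own transcript contains hairpins that the pair can cut. DGCR8 went from 7.52 ± 0.04 to 8.03 ± 0.15 (SD, n = 3 each), a log2 change of 0.51 (SE 0.09) with a limma adjusted p of 0.314 over all genes and 0.00338 over the list alone. DICER1, which cuts precursor microRNAs in the cytoplasm, had a log2 change of 0.32 (SE 0.10), with a limma adjusted p over the list alone of 0.0633, and 0.0140 with the replicate number as a block. AGO1, an Argonaute protein that holds mature microRNAs, had a log2 change of -0.15 (SE 0.07). The list as a whole had a mean log2 change of -0.02 and a median of -0.04, while camera put it on the higher side with an adjusted p of 0.993.

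The next comparison asked which genes differed between shDrosha and EV cells. Few genes passed, and most of those that did were microRNA genes with higher signal. MIR223, a microRNA gene of the myeloid lineage, rose 6.34-fold, from 7.39 ± 0.32 to 10.06 ± 0.12 (SD, n = 3 each). MIR222 rose 5.12-fold, and MIR24-2 and MIR27A, neighbours in a single cluster, rose 2.90-fold and 2.45-fold. MIR146A, a microRNA gene induced by NF-kB signalling, rose 2.48-fold, MIR15A 1.92-fold and MIRLET7G 1.60-fold. PRDX3, the mitochondrial peroxiredoxin that removes hydrogen peroxide, fell from 8.78 ± 0.04 to 7.62 ± 0.10 (SD, n = 3 each).

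Over 18417 genes, limma found 10 past an adjusted p of 0.05, 8 higher and 2 lower in shDrosha. The log2 changes were 2.66 (SE 0.15, adjusted p = 0.000303) for MIR223, 2.36 (SE 0.20, adjusted p = 0.00498) for MIR222 and 1.53 (SE 0.09, adjusted p = 0.000303) for MIR24-2. They were 1.31 (SE 0.15, adjusted p = 0.0215) for MIR146A, 1.29 (SE 0.14, adjusted p = 0.0167) for MIR27A, 0.94 (SE 0.09, adjusted p = 0.00926) for MIR15A and 0.68 (SE 0.07, adjusted p = 0.0215) for MIRLET7G. PRDX3 had a log2 change of -1.16 (SE 0.08, adjusted p = 0.000996), which left 44.8% of the EV level (95% confidence interval 39.5 to 50.7%). Each of these genes moved the same way in 3 of 3 pairs. The remaining gene, RNU5B-1, a spliceosomal RNA gene chosen after its values were seen, rose by 0.69 (SE 0.09, adjusted p = 0.0433). Leaving out EV replicate 3 or shDrosha replicate 2 left 4 genes each, and leaving out EV replicate 2 left 6. MIRLET7G was past the threshold in none of the 6 fits that left out 1 array, with an adjusted p of 0.0907 to 0.147, whereas MIR223, MIR222, MIR24-2 and PRDX3 were past it in all 6. MIR146A lost its call without EV replicate 1 (adjusted p = 0.114), EV replicate 3 (0.105), shDrosha replicate 2 (0.118) or shDrosha replicate 3 (0.135). MIR27A lost its call without EV replicate 2 (0.0907), EV replicate 3 (0.0794) or shDrosha replicate 2 (0.102), and MIR15A without EV replicate 3 (0.0571) or shDrosha replicate 2 (0.0636).

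**Figure D1:**
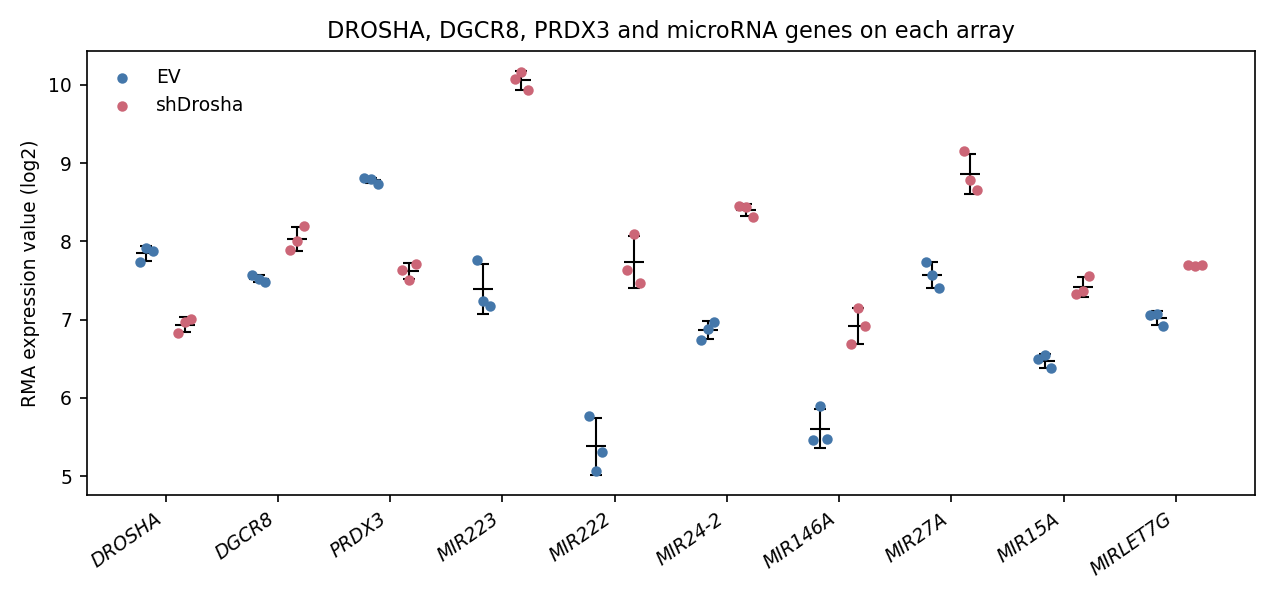
Log2 expression value (vertical axis) of DROSHA, DGCR8, PRDX3 and the 7 microRNA genes past the threshold on each of the 3 EV and 3 shDrosha arrays; points are arrays, and bars are the mean and 1 SD. MIR223 lies at 7.39 in EV and 10.06 in shDrosha on average, and PRDX3 at 8.78 and 7.62.

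Same-numbered arrays deviated together, so the replicate number was also fitted as a block. With the block, limma found 22 genes, 18 higher and 4 lower, which included all 10 found without it. Fitted over every row of the table, 4 rows passed without the block and 0 with it (2377 at an unadjusted p under 0.05). MicroRNA genes made up 12 of the 22, and the added ones were MIR142 (log2 change 1.11, adjusted p 0.0292 with the block), MIR21 (0.62, 0.0292), MIR221 (0.86, 0.0361), MIRLET7F1 (0.85, 0.0361) and MIR181B1 (0.57, 0.0453). The transcripts MIR17HG (0.61, 0.0361) and DLEU2 (0.70, 0.0141), which carry the miR-17 and miR-15a clusters, were also among them. The other added genes were MSL3B (0.96, 0.00340), LIPN (1.23, 0.0342), FAM200B (0.57, 0.0459), API5 (-0.59, 0.0470) and MPEG1 (-0.62, 0.0446), and the arrays of the 2 groups overlapped for MPEG1. DLEU2, MIR21, MIR221, MIR181B1, LIPN, FAM200B and MPEG1 fell outside the naming rule and were chosen after their values were seen.

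Without the block, 5 further genes named by rule on the higher side and 2 on the lower side did not pass. The log2 change was 0.61 (SE 0.08, adjusted p = 0.0544) for MIR17HG, 1.11 (SE 0.15, adjusted p = 0.0666) for MIR142 and 0.73 (SE 0.10, adjusted p = 0.0722) for MIR23A. It was 0.96 (SE 0.13, adjusted p = 0.0722) for MSL3B and 0.85 (SE 0.14, adjusted p = 0.205) for MIRLET7F1. On the lower side it was -0.62 (SE 0.12, adjusted p = 0.453) for the long noncoding RNA LCAL1 and -0.59 (SE 0.14, adjusted p = 0.878) for API5, an inhibitor of apoptosis. MIR17HG and MIR23A passed once arrays were centred on their medians (adjusted p = 0.0370 and 0.0448), and so did MIR142 (0.0448). MIR142 also passed without EV replicate 1 (0.00672).

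Across all 18417 genes the median log2 change was -0.01, and the 95th percentile of its absolute value was 0.222. A log2 change of at least 0.58 in either direction was seen for 29 genes and of at least 1 for 8. At an unadjusted p of 0.05 limma counted 872 genes, 436 higher and 436 lower, against 920.85 by chance, and 1528 with the block. The arrays of the groups did not overlap for 1903 genes (10.3%), where chance gives 10% if arrays are independent. Same-numbered arrays deviated together, so this share and the count without the block do not exclude an excess of changed genes.

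**Figure D2:**
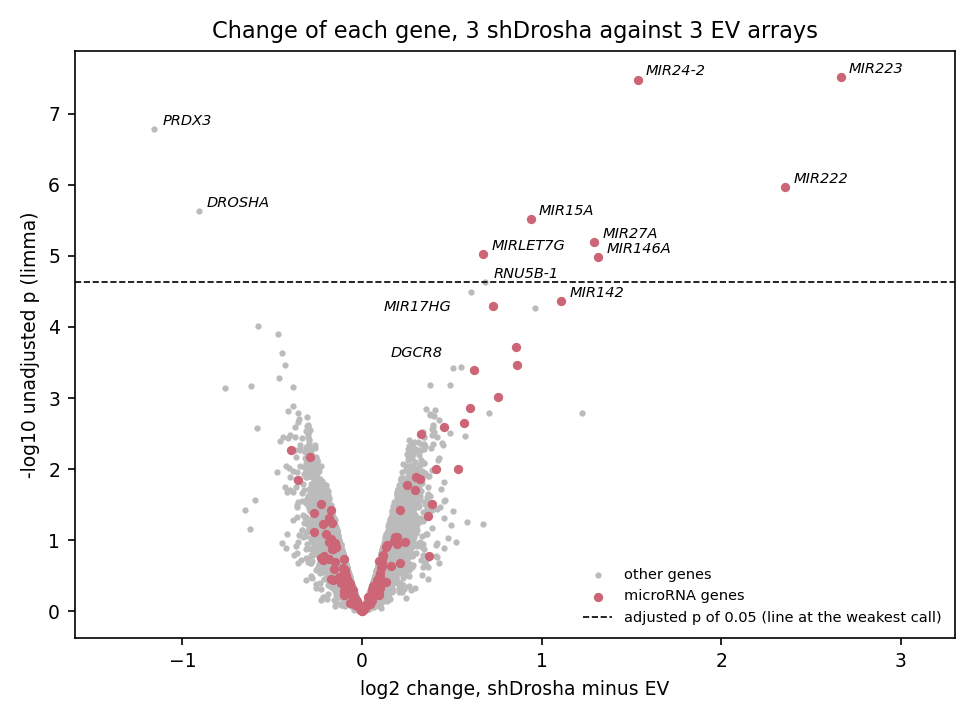
Log2 change, shDrosha minus EV (horizontal axis), against -log10 of the unadjusted limma p (vertical axis) for each gene, with microRNA genes in red and all others in grey. The dashed line is drawn at the weakest of the 10 calls, and 7 of the genes at or above it are microRNA genes.

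The third comparison asked whether microRNA genes moved as a group, since the array's probes for these genes read primary or precursor transcripts and not the mature microRNA. Of 173 microRNA genes at 126 loci, 7 rose and 0 fell over all genes, at 6 loci. When adjusted over the list alone, 17 rose, 0 fell and 156 did not pass, and the 17 lay at 14 loci with a mean log2 change of 1.04. Besides the 7 above and MIR142, MIR23A, MIRLET7F1, MIR221, MIR21 and MIR181B1, they were MIR301A (log2 change 0.75), MIR15B (0.60), MIR93 (0.46) and MIR181B2 (0.33). Neighbours at the same loci did not all rise. Those of MIR15A (MIR16-1, 0.11), MIR15B (MIR16-2, -0.16) and MIR93 (MIR25, 0.10, and MIR106B, 0.25) did not pass over the list alone. Neither did those of MIRLET7F1 (MIRLET7A1, -0.10, and MIRLET7D, 0.04), MIR181B1 (MIR181A1, 0.30) and MIR181B2 (MIR181A2, 0.06). Some of these neighbours were dim: the EV mean was 3.63 for MIR16-1 and MIR16-2 and 4.79 for MIR181A1, where the median gene lay at 6.96. For such dim probe sets a missing rise says little. MIR25, MIR106B and MIRLET7D were brighter, at 7.88, 7.37 and 7.52. MIR24-2, MIR27A and MIR23A rose together, and so did MIR222 and MIR221. With the block, 20 rose and 1 fell when adjusted over the list alone. MIR103A2 (0.41), MIR126 (0.53) and MIR19B2 (0.30) were added on the higher side, and the one lower was MIR129-2, with a log2 change of -0.40 (adjusted p over the list alone 0.0338, against 0.0517 without the block).

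MicroRNA genes made up 0.939% of the genes fitted and 7 of the 10 past the threshold (Fisher's exact test, p = 6.7e-13, in which neighbouring genes of 1 cluster are not independent). The mean log2 change of the whole set was 0.10 and the median -0.003, which differ in sign. Camera gave p = 0.00298 on the higher side with its preset correlation and p = 0.0576 with an estimated correlation. Limma's rotation test fry, over the set (n = 173 genes on 6 arrays), gave p = 0.0228 for a shift one way and p = 6.6e-07 for change in either direction. Without shDrosha replicate 1 the mean was 0.09 and camera gave p = 0.0719 (n = 173 genes on the other 5 arrays). By their mean over all 6 arrays, 132 of the 173 microRNA genes were dimmer than the median gene. Of these, 7 rose when adjusted over the list alone, against 10 of the 41 brighter ones (Fisher's exact test, p = 0.00112). With brightness taken from the EV arrays, which a rise does not touch, Fisher's exact test gave p = 0.0269.

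Some of the 17 risen microRNA genes lie within the span of protein-coding genes, with strand not considered, and 6 of these hosts were measured. VMP1, which contains MIR21, had a log2 change of 0.00, and WDR82, which lies with MIRLET7G, one of 0.04. SKA2, with MIR301A, had a log2 change of 0.25 and SMC4, with MIR15B, one of 0.22. MCM7, with MIR93, had -0.04 and NR6A1, with MIR181B2, had -0.11. None of the 6 passed the limma threshold over all genes. Of the 25 transcripts fixed beforehand as microRNA hosts, 14 were measured. None passed over all genes, 2 had an unadjusted p under 0.05, and the same number, MIR17HG and DLEU2, rose when adjusted over the list alone (adjusted p = 0.000455 and 0.0114). The log2 changes of SMC4 and MIRLET7BHG were 0.22 and -0.08. The list's mean was 0.08 and its median -0.01, and camera gave an adjusted p of 0.250 on the higher side.

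The last comparison asked whether gene lists fixed before the data were examined had shifted. They were 25 in number, and 450 of their 515 members were measured. Camera put 1 list past an adjusted p of 0.05, the mitotic G2/M genes, which sat higher in shDrosha. With the replicate block there were 2, the added one being neutrophil granule and granulocyte markers on the lower side, and with an estimated correlation or with fry there were 0. At an unadjusted camera p of 0.05, 7 lists were counted.

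Of the 22 G2/M genes, all measured, 19 had a positive and 3 a negative log2 change, with a mean of 0.10 and a median of 0.10. The camera adjusted p was 0.00181, and the adjusted p was 0.831 with an estimated correlation and 0.876 by fry. None of its members passed limma's threshold over all genes or when adjusted over the list alone, and 3 had an unadjusted p under 0.05. CDK1, the kinase that drives entry into mitosis, had a log2 change of 0.32, its partner cyclin CCNA2 one of 0.24, the mitotic kinesin KIF20A one of 0.20 and the spindle protein DLGAP5 one of 0.25. Without EV replicate 1 the list's mean was 0.05 (adjusted p = 0.190), and without shDrosha replicate 3 it was 0.07 (adjusted p = 0.0892). The DNA replication list did not pass, with 9 of 20 measured genes higher, 11 lower, a mean log2 change of -0.01 and a camera adjusted p of 0.993. Its mean ran from -0.05 to 0.03 when 1 array was left out. In it, none passed over all genes or over the list alone and 2 had an unadjusted p under 0.05, MCM3 (-0.30) and UHRF1 (-0.29), while the values of MCM2 and RRM1 were 0.11 and 0.17.

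Reported targets of microRNAs did not pass as groups. Of 15 measured let-7 oncofetal targets (19 listed), 9 were higher and 6 lower, with a mean log2 change of 0.06 and a camera adjusted p of 0.171. None passed over all genes or when adjusted over the list alone, 2 had an unadjusted p under 0.05, and with the block the same number, DICER1 and the cyclin CCND2 (0.27), rose when adjusted over the list alone (adjusted p = 0.0351 and 0.0374). IGF2BP3, an RNA-binding protein, had a log2 change of 0.17 and ARID3B one of -0.09. Without shDrosha replicate 1 the list reached a mean of 0.12 and an adjusted p of 0.0226, but the mean was 0.01 without shDrosha replicate 2 (adjusted p = 0.700) and 0.03 without EV replicate 1 (adjusted p = 0.572). Among 36 measured targets of other blood-cell microRNAs (40 listed), 23 were higher and 13 lower, with a mean of 0.03 and an adjusted p of 0.275. None passed over all genes or over the list alone and 0 had an unadjusted p under 0.05. Leaving out 1 array moved the mean of these targets between 0.02 and 0.05 (camera adjusted p = 0.145 to 0.751). The survival factor MCL1 had a log2 change of 0.18, the methyltransferase DNMT3B -0.18, the signalling adaptor TRAF6 0.17 and the cyclin CCND3 0.21.

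Markers of stem and progenitor cells did not pass as a group. Of the 20 measured (21 listed), 11 were higher and 9 lower, with a mean log2 change of 0.00 and a camera adjusted p of 0.993. SPINK2 had -0.20, LMO2 -0.13, MEIS1 0.16 and MSI2 0.07. The HOX list had 10 of 19 members measured, 5 higher and 5 lower, with a mean of -0.02, a median of 0.001 and an adjusted p of 0.985. HOXB7 had -0.18, HOXB8 -0.21, PBX3 0.15 and HOXB4 0.13. No member of either list passed over all genes or when adjusted over the list alone, and 1, HOXB7, had an unadjusted limma p under 0.05.

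Among lineage markers, the list with the most one-sided values was that of neutrophil granule and granulocyte genes, 17 of 20 lower and 3 higher (22 listed). Its mean log2 change was -0.08, with a camera adjusted p of 0.116, or 0.0208 with the replicate block. With an estimated correlation the adjusted p was 0.858, and 0.717 with the block as well. Lactoferrin (LTF) had a log2 change of -0.24, LCN2 -0.22, BPI -0.16 and OLFM4 0.18. Without EV replicate 3 the list's mean was -0.19 and its adjusted p 0.000640, but the mean was -0.01 without EV replicate 2 (adjusted p = 0.541) and turned to 0.01 without shDrosha replicate 3 (adjusted p = 0.684). Lymphoid markers were lower in 15 of 20 and higher in 5 (22 listed), with a mean of -0.07 and an adjusted p of 0.116, and CD3D had -0.25, VPREB1 -0.27, CD3G -0.26 and KLRD1 0.16. Without EV replicate 3 the lymphoid mean was -0.10 (adjusted p = 0.0158), and without shDrosha replicate 1 it was also -0.10 (adjusted p = 0.0314). Without any one of the other arrays it was -0.06 to -0.05 (adjusted p = 0.158 to 0.381), and the adjusted p on all arrays was 0.858 with an estimated correlation.

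Erythroid markers had a mean log2 change of 0.04 (17 of 23 measured, 13 higher, 4 lower, camera adjusted p = 0.505), with -0.24 for the membrane transporter SLC4A1, -0.11 for GATA1, 0.34 for CA1 and 0.07 for KLF1. Megakaryocyte and platelet markers had a mean of 0.06 (18 of 18 measured, 12 higher, 6 lower, adjusted p = 0.436), with 0.28 for LTBP1, 0.10 for RAB27B, 0.23 for MMRN1 and 0.08 for PF4. Their mean was 0.22 without EV replicate 1 (adjusted p = 0.000581) and 0.16 without shDrosha replicate 2 (adjusted p = 0.0423), but turned to -0.07 without EV replicate 2 (adjusted p = 0.583) and to -0.08 without shDrosha replicate 1 (adjusted p = 0.419). Monocyte, macrophage and dendritic markers had a mean of 0.01 (23 of 25 measured, 12 higher, 11 lower, adjusted p = 0.985), with -0.26 for C1QB, 0.20 for MSR1, 0.34 for CX3CR1 and -0.18 for CD300E. With the block, the chemokine receptor CX3CR1 rose when adjusted over the list alone (adjusted p = 0.0424). Mast cell, basophil and eosinophil markers had a mean of 0.09 (12 of 17 measured, 10 higher, 2 lower, adjusted p = 0.307), with 0.27 for PRG2, 0.36 for CLC, 0.21 for RNASE2 and -0.12 for HDC. The antigen-presenting MHC class II list had a mean of -0.01 (8 of 11 measured, 3 higher, 5 lower, adjusted p = 0.985), with -0.10 for HLA-DOA and -0.04 for its regulator CIITA. Stromal and endothelial markers had a mean of 0.04 and a median of -0.01 (15 of 15 measured, 7 higher, 8 lower, adjusted p = 0.429), with 0.19 for KDR, 0.29 for DCN, -0.16 for CLDN5 and 0.11 for FBN1. Single arrays moved other lineage means that did not pass: the erythroid mean ran from -0.04 without shDrosha replicate 3 to 0.13 without EV replicate 3, the monocyte mean from -0.03 without EV replicate 3 to 0.08 without EV replicate 2, the MHC class II mean from -0.09 without shDrosha replicate 2 to 0.13 without shDrosha replicate 1, and the mast cell mean from 0.03 without shDrosha replicate 3 to 0.14 without shDrosha replicate 2. The stromal mean ran from 0.02 to 0.07 when 1 array was left out. In the lineage lists from neutrophil to stromal, no member passed limma's threshold over all genes or when adjusted over the list alone. The members with an unadjusted p under 0.05 were 2 neutrophil, 3 lymphoid, 1 erythroid, 1 monocyte and 2 stromal genes, and 0 of the megakaryocyte, mast cell and MHC class II lists.

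Inflammatory and interferon genes did not pass. NF-kB and inflammatory genes had a mean log2 change of -0.001 and a median of 0.01 (23 of 24 measured, 13 higher, 10 lower, camera adjusted p = 0.993), with -0.23 for the chemokine CXCL1, 0.17 for TRAF6, -0.16 for IL6 and -0.17 for CCL4. Interferon response genes had a mean of -0.10 (21 of 23 measured, 4 higher, 17 lower, adjusted p = 0.436), with -0.31 for USP18, -0.23 for IFIT1, -0.14 for the RNA sensor RIGI and -0.10 for IFIH1. The interferon value turned on single arrays. Its mean was -0.43 without EV replicate 3 (adjusted p = 4.3e-07) and -0.28 without shDrosha replicate 1 (0.0571), but 0.14 without EV replicate 2 (0.178), 0.18 without shDrosha replicate 3 (0.190) and 0.0006 without EV replicate 1 (0.865). In both lists no member passed over all genes or over the list alone, and 0 had an unadjusted limma p under 0.05.

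Genes of the p53 response had a mean log2 change of -0.05 (20 of 22 measured, 6 higher, 14 lower, camera adjusted p = 0.143), with -0.18 for TRIAP1, -0.17 for GDF15, 0.18 for ZMAT3 and -0.13 for XPC. Without shDrosha replicate 2 their mean was -0.08 and the adjusted p 0.0290, but the mean was -0.02 without shDrosha replicate 1 (adjusted p = 0.664) and -0.03 without EV replicate 1 (adjusted p = 0.363). Apoptosis regulators had a mean of -0.02 (18 of 20 measured, 6 higher, 12 lower, adjusted p = 0.694), with -0.22 each for the death-promoting HRK and BAD, 0.18 for MCL1 and 0.29 for BCL2A1. Immediate early and heat shock genes had a mean of 0.08 (14 of 17 measured, 11 higher, 3 lower, adjusted p = 0.116), with 0.20 for the phosphatase DUSP1, 0.21 for FOS, 0.15 for KLF6 and 0.11 for FOSB. Their mean was 0.09 without EV replicate 1 (adjusted p = 0.0273) and 0.11 without shDrosha replicate 1 (adjusted p = 0.0386), but 0.06 without shDrosha replicate 2 (adjusted p = 0.174) or without EV replicate 3 (adjusted p = 0.225), and the adjusted p on all arrays was 0.831 with an estimated correlation. Unfolded protein and integrated stress response genes had a mean of -0.05 (16 of 16 measured, 5 higher, 11 lower, adjusted p = 0.436), with -0.12 for SESN2, -0.10 for SDF2L1, -0.14 for CHAC1 and -0.17 for HERPUD1.

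Ribosome biogenesis genes had a mean log2 change of -0.02 (20 of 22 measured, 10 higher, 10 lower, camera adjusted p = 0.830), with 0.20 for RRN3, -0.16 for WDR43, -0.13 for NOLC1 and -0.10 for the nucleolar protein NCL. Cholesterol and lipid synthesis genes had a mean of -0.06 (13 of 16 measured, 4 higher, 9 lower, adjusted p = 0.133), with -0.19 for LSS, -0.22 for HMGCS1, -0.15 for MVD and -0.13 for DHCR7. Their mean ran from -0.09 without shDrosha replicate 3 (adjusted p = 0.0506) to -0.03 without shDrosha replicate 1 (adjusted p = 0.481), and was -0.04 without EV replicate 3 (adjusted p = 0.365). Glycolysis and hypoxia genes had a mean of 0.05 (17 of 18 measured, 9 higher, 8 lower, adjusted p = 0.623), with 0.48 for the hypoxia-induced BNIP3, 0.17 for ENO2, 0.09 for NDRG1 and 0.08 for HK2. With the block, BNIP3 rose when adjusted over the list alone (adjusted p = 0.00846), and without EV replicate 1 the list's mean was 0.16 (adjusted p = 0.0118). That mean turned to -0.02 without EV replicate 3 (adjusted p = 0.670) and to -0.05 without shDrosha replicate 1 (adjusted p = 0.440). In the lists from p53 to hypoxia, no member passed limma's threshold over all genes or, without the block, over the list alone. The members with an unadjusted p under 0.05 were 1 p53, 2 apoptosis, 2 immediate early and 1 cholesterol gene, and 0 of the other lists.

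**Figure D3:**
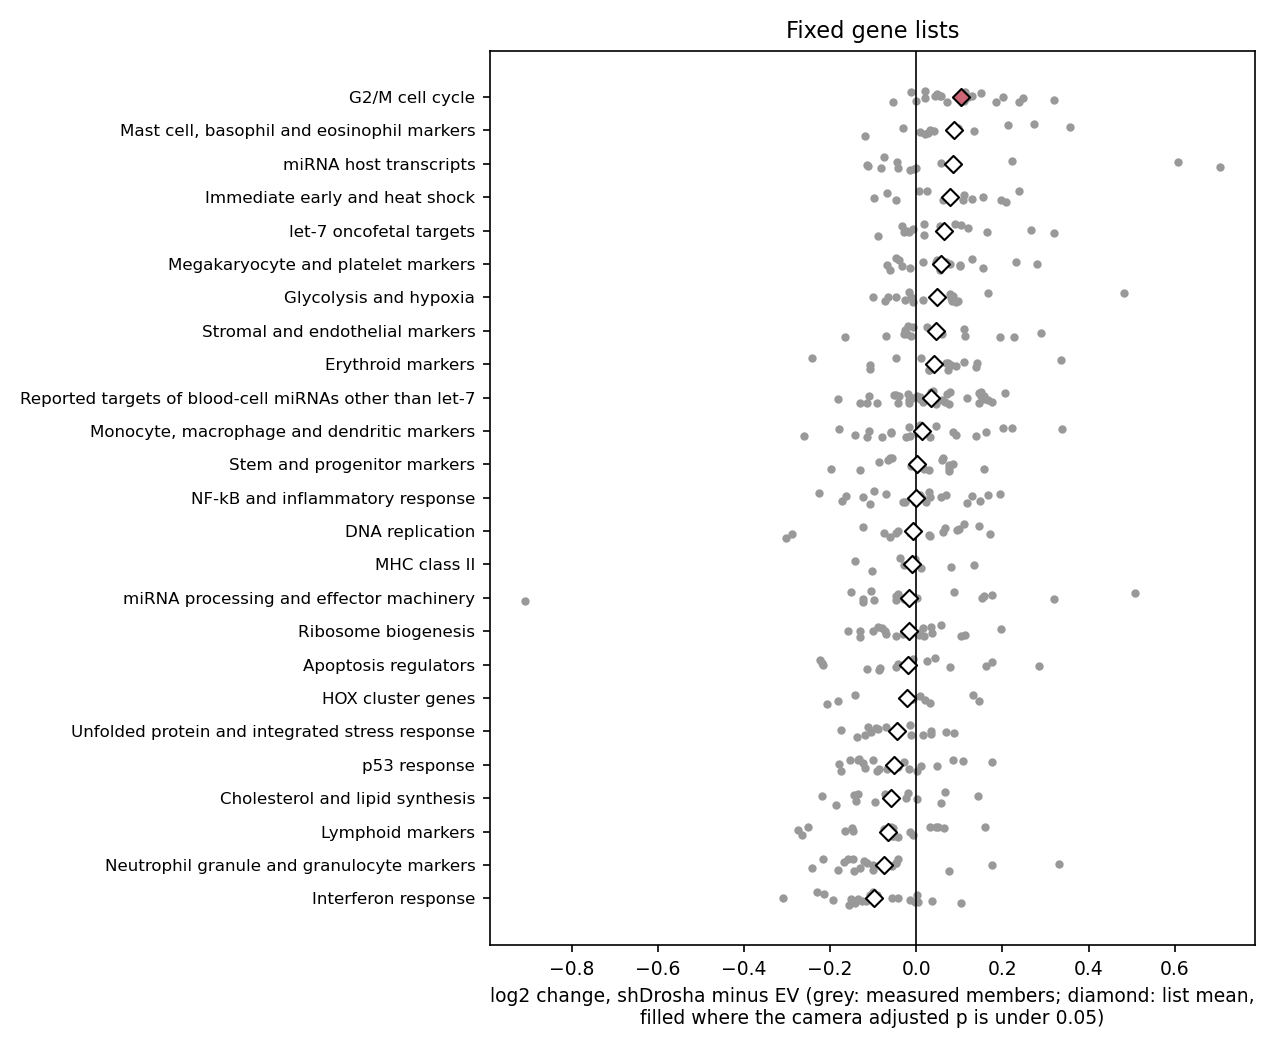
Log2 change, shDrosha minus EV (horizontal axis), of each measured member (grey points) of the 25 fixed gene lists (rows), with diamonds at the list means. The filled diamond marks the G2/M list, the only one with a camera adjusted p under 0.05 without the replicate block, at a mean of 0.10, a call lost with an estimated correlation (adjusted p = 0.831).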

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

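The tests on other small RNA genes and on noncoding hosts of microRNA genes, on the estimated correlation and the DNA replication genes for the G2/M list, and on further falling genes beside PRDX3 were chosen after the result was seen.

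One result lies in rows that the comparisons of genes leave out. Of 13837 rows named by no single gene, 1 passed the threshold in a fit of every row. It was row 7894918, with 4.89 ± 0.23 in EV and 3.18 ± 0.05 in shDrosha (SD, n = 3 each). Its log2 change was -1.71 (SE 0.12), with a limma adjusted p of 0.0196 over all rows, and 0.103 with the replicate block. Only 5.95% of rows were dimmer.

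The rise of microRNA genes could be an array-wide rise of small RNA signal, higher transcription of the genes around them, or less cutting of primary transcripts. The tables argue against the first as the whole cause of the rise of the 17 risen microRNA genes. The 195 small nucleolar and spliceosomal RNA genes changed by 0.0406 on average (SE 0.0114, log2), below 50% of the mean of these 17 (0.519). That bound comes from genes picked because they had risen, and it does not reach the set as a whole. For the mean of 0.0987 over all 173 microRNA genes, an array-wide rise stays open. For the 6 risen microRNA genes inside measured protein-coding hosts, the test of the second reads only transcription that a gene shares with its host. Strand was not considered, and a host on the opposite strand shares none. On average over the 6, the tables argue against such shared transcription as the whole cause. The 6 hosts changed by 0.0583 on average (SE 0.0592), against a bound of 0.286 that also comes from genes picked because they had risen. For each of the 6 taken singly, and as part of the cause, higher transcription stays open: SKA2 and SMC4 changed by 0.25 and 0.22, the others by -0.11 to 0.04. For MIR15A it stays open, because DLEU2, the noncoding transcript that carries it, changed by 0.705 (SE 0.158) against a bound of 0.469, and as DLEU2 is itself the primary transcript, more transcription and less cutting cannot be told apart; for the other 10, MIR223, MIR222 and MIR24-2 among them, it was not tested, as no host was measured. Less cutting also stays open as a hypothesis: the 6 microRNA genes exceeded their hosts by 0.515 (SE 0.0418), but they were picked because they had risen, so this difference does not count for it.

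The higher G2/M list could reflect a larger share of cycling cells, a single pair of arrays, or genes that vary together within groups. The list's mean was above 0 in 3 of 3 pairs, from 0.0300 to 0.163, so its sign did not rest on a single pair. Its size may, because the list was picked for its high mean over these same pairs. Without EV replicate 1 the mean was 0.05 (camera adjusted p = 0.190). DNA replication genes (9 higher, 11 lower) had a mean of -0.00853 (SE 0.0279 over genes), below the bound of 0.0517, which goes against a larger share of cycling cells. That error takes genes as independent, though their correlation was estimated at 0.260. Without 1 array the mean ran from -0.0455 to 0.0342, so a larger share of cycling cells stays open. Genes that vary together stay open too, as camera gave p = 0.119 for the list alone once their correlation of 0.185 was estimated. The 10 splits are too few for a share under 0.05, with a mean of 0.103 in the real split, 0.0999 as the highest of the others, 0.0835 as the highest of the others that part all 3 pairs, and 1 split at the real value.

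The log2 change of PRDX3 was at least as large as that of the targeted gene, and a general fall of antioxidant genes or an action of the hairpin on PRDX3 itself could account for it. Against the first, 17 other peroxiredoxin, thioredoxin and other antioxidant genes had a mean log2 change of 0.0380 (SE 0.0271), and the bound set for such a fall was -0.3. The hairpin's sequence is not given, so its action on PRDX3 and an effect of less DROSHA cannot be told apart, and the 0 further genes past the threshold on the lower side (without the replicate block) decide nothing. No second hairpin and no non-targeting hairpin was measured. For the microRNA genes, DGCR8 and the G2/M list too, carrying any hairpin and having less DROSHA therefore cannot be told apart.

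For the count of genes past the threshold, the 10 splits are again too few for a share under 0.05: the real split gave 10 genes and the highest of the others 0, so 1 split reached it. Because the numbers pair the arrays, the real split compares best with those that part all 3 pairs. There are 4 of these, and the others among them gave 0 genes, with the block as well, while the 6 that part 1 pair also gave 0. For the mean of all microRNA genes, where the splits are as few, the real split gave 0.0987 and the others at most 0.0635 (0.0376 among those that part all 3 pairs), so 1 split reached it.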

How the results depend on the processing

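One alternative, every row of the table together with the replicate block, was chosen after seeing the data. The directions of the DROSHA, microRNA and G2/M results, and of every named gene past the threshold, were the same under all alternatives run. The count of 10 genes stayed within 1.5 times under centring, quantile normalization, the filter on dim genes, both eBayes options, array weights, the mean of probe sets, an adjusted p under 0.1 and a fold of at least 1.5 on top of the adjusted p. It was 22 with the replicate block, 26 at an unadjusted p under 0.05 with a fold of at least 1.5 (19 higher, 7 lower), and 4 over every row of the table (3 of them shared with the 10). It was 0 over every row with the replicate block, where limma counted 2377 rows at an unadjusted p under 0.05, and the fit without the block 1677. Leaving out 1 array gave 4 to 8 genes.

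For DROSHA the log2 change was -0.91 over every row, where its adjusted p was 0.0956. It ran from -0.96 to -0.85 without 1 array, with an adjusted p of 0.0189 to 0.0636 and the call lost in 3 of 6 fits. The range of the adjusted p over the other alternatives was 0.00320 to 0.0956. The mean of the microRNA genes was 0.0987 with an estimated correlation (p = 0.0576) and ran from 0.0855 to 0.112 without 1 array, and it was 0.215 without the dimmest 30% of genes, which holds fewer genes (p = 5.8e-05). Of the gene lists, 2 passed with the replicate block, 0 with an estimated correlation, 0 with fry and 0 to 4 without 1 array: 3 without EV replicate 1, 4 without EV replicate 3, 4 without shDrosha replicate 1, 3 without shDrosha replicate 2 and 0 without shDrosha replicate 3. Every fit without 1 array has fewer samples; for the other differences the cause was not tested.

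Among single named genes other than DROSHA, 15 of the fits without 1 array lost a call and 1 gained one, and 80 kept their side of the threshold. Under the other settings run gene by gene, which do not include the fit of every row, 13 gained a call, 0 lost one and 110 kept their side. In the fit of every row, 3 of the 10 genes remained, and why the others did not was not tested. For single lists, 11 of the fits without 1 array gained a call, 2 lost one and 137 kept their side, and under the other settings 1 gained, 2 lost and 197 kept. Apart from the genes and lists given with blocked values, the replicate block changed no other call. The seed-site sets and their alternatives were not run, for want of transcript sequence. The files give no background level, so how far signal over background limits the dimmer probe sets was not measured.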

Other observations

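The classes below were chosen after the data were seen, and none of their means was part of a comparison set beforehand. Their genes were fitted singly in the main comparison, in which RNU5B-1 passed. Genes typed as small nucleolar or spliceosomal RNA also served above, in the test of an array-wide rise of small RNA signal. Among 9 gene classes, C/D box small nucleolar RNA genes, whose RNAs guide methylation of ribosomal RNA, had a mean log2 change of 0.06 over 115 genes, with 69.6% of them higher in shDrosha. Camera gave an adjusted p of 0.000682 over the 9 classes, and an adjusted p of 0.493 with an estimated correlation. The H/ACA class, whose RNAs guide pseudouridylation, had a mean of -0.01 over 61 genes (camera adjusted p = 0.610), which turned to 0.01 with arrays centred on their medians. Whether these classes differ was not tested. No gene of either class passed limma's threshold over all genes, with 9 and 4 at an unadjusted p under 0.05.

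Olfactory receptor genes, which are silent in most tissues, had a mean log2 change of 0.05 over 361 genes and a mean level of 6.11 (adjusted p = 0.00146, and 0.493 with an estimated correlation). Core histone genes had a mean of 0.04 over 66 genes (adjusted p = 0.0354, and 0.493 with an estimated correlation). Cytosolic ribosomal protein genes had a mean of -0.0002 over 62 genes (adjusted p = 0.512), which was 0.02 after centring, and mitochondrial ribosomal protein genes one of 0.02 over 74 genes (adjusted p = 0.146). Spliceosomal RNA genes had a mean of 0.07 and a median of 0.04 over 20 genes (adjusted p = 0.0916, 0.0353 with the replicate block, and 0.493 with an estimated correlation). Among them only RNU5B-1 passed limma's threshold over all genes, with a log2 change of 0.69. The 175 genes typed as small nucleolar RNA in the RefSeq table, where the C/D box and H/ACA classes were taken by symbol, had a mean of 0.04 (adjusted p = 0.0289, and 0.493 with an estimated correlation). Long noncoding RNA genes had a mean of -0.02 over 632 genes (adjusted p = 0.0916), which was -0.0004 with arrays centred and -0.01 with quantile normalization. The means of the C/D box, olfactory receptor and histone classes stayed above 0 with arrays centred or quantile normalized.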
